A study of Mus musculus with 6 samples.

How the data were processed

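Gene expression was measured in the livers of 3 WT and 3 Gα12-deficient male mice. Per the labels' protocols, cRNA labelled with Cy3 was made from 0.5 µg of RNA for each array, and RNA quality was checked on a Bioanalyzer, whose readings are not given in the sources used here. The labels describe 3 animals per group, so each array was taken as 1 animal. Groups and replicate numbers came from the sample titles. All 6 arrays lay on 1 slide and were scanned once, per the file headers. The WT arrays filled row 1 of the slide and the knockout arrays row 2, so slide row and genotype cannot be told apart. The rows differed in technical measures. Spots marked as non-uniform numbered 2, 4 and 6 on WT replicates 1 to 3 and 145, 158 and 98 on knockout replicates 1 to 3. The software's background error estimate was 5.97 to 8.60 on WT arrays and 10.5 to 13.3 on knockout arrays. Whether this changed which probes were well above background there was not tested.

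Per the file headers and the submitters' processing notes, the spots were read with Agilent Feature Extraction 10.7.3.1. The deposited scanner files hold the spot intensity on a linear scale: a processed intensity, from which background had been subtracted and in which low values had been replaced by a floor, and the raw median intensities of spot and local background. The deposited series matrix holds log2 values, found by comparison to be the log2 of the processed intensity plus a constant for each array, not centred for each probe. Its column medians were 4.41, 4.17 and 4.70 for WT replicates 1 to 3 and 4.32, 4.44 and 4.52 for the knockout. How the authors chose those constants stays unknown.

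Starting from the processed intensity of 62976 spots, log2 values were taken and the 75th percentile of the non-control spots was subtracted on each array. Control spots and spots that the scanner software marked as non-uniform or population outliers were left out, and the log2 values of a probe's spots were averaged. This gave 55324 of 55681 probes a value on all 6 arrays, and 357 were lost to outlier marks. Probes well above background on at least 3 of the 6 arrays, whatever their group, were kept (23132). No non-control spot was saturated. The probes well above background numbered 22951, 23530 and 28752 on WT replicates 1 to 3 and 21778, 20953 and 22585 on knockout replicates 1 to 3. Where no array of a group had a probe well above background, a fold is given as a lower bound ("at least"), from the mean of the brighter group against the mean, over the dim group's arrays, of the higher of the lowest signal well above background and the probe's own signal. That lowest signal is not a limit of detection. Such a bound therefore holds for this scaling only, and other scalings gave smaller differences for some of these genes.

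The files name probes by accession and not by symbol, although the plan had assumed symbols. Symbols were therefore taken from a RefSeq gene table of assembly GRCm38.p6 by unversioned accession. Of the probes, 26762 matched, for 20284 genes, and 28919 did not. The arrays were designed on an older build, so the table served only for names and for the order of genes along chromosomes, and no coordinates of it are given. A gene was represented by its kept probe with the highest mean. Of 2737 genes with several kept probes, 1180 had probes with differences of opposite sign, and for 1076 the probes differed by over 1 log2 unit.

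Knockout minus WT was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) over the kept probes, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene kept the adjusted p of its probe, so that genes were not adjusted over genes alone except with the mean over probes. Gna12 was not among the kept probes, so its values come from the same fit over all probes. For 34 gene lists with at least 5 measured members, limma's camera with a preset correlation of 0.01 compared each list with all other genes, adjusted over the lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in a direction without reference to other genes, were run beside it. Counts described as adjusted over the list alone come from a Benjamini-Hochberg adjustment of limma's p-values within that list. No adjustment was made across the 34 lists, some of which share genes, and there were 16 such passes in all, so they are descriptive. Genes beside Gna12 were compared with the others by Fisher's exact test, and correlations between arrays by an exact permutation test over the 10 splits of the arrays.

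The groups, tests, lists, alternatives and rule for naming genes were fixed before the data were examined, except where the text says otherwise. The rule named Gna12 first, then up to 12 genes with the largest difference in each direction among genes past the threshold whose groups did not overlap. Because fewer than 6 passed in either direction, 6 in each direction were taken in order of p from genes with an unadjusted p below 0.01 and non-overlapping groups. Symbols that are only clone or model names were left out. Up to 4 members of each list with the smallest p were added. Ren1, Gapdh and the clone-named genes called with probe means were chosen after their values were seen. Of the genes named by the rule, 139 had values under all 4 other scalings, and 138 of them kept their sign (Chil3 did not). Another 4 had values under 3 of the scalings and kept their sign there.

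The comparison was repeated with normexp background correction with an offset of 50, with quantile normalization, scaling to the median of kept probes, the series matrix, other filters, trend and robust estimation, array weights, the replicate number as a block, each array left out in turn, the mean over a gene's probes, probes with outlier marks left out, other list tests and other neighbourhood sizes. The files hold no mean spot signal, so normexp used the median signal. The slide could not serve as a block because there was 1.

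The limma step was tested on simulated data for this comparison, with 3 arrays against 3 and 10 runs over 23132 probes with the real means and spreads, drawn independently for each probe. With the spread of all 6 arrays, 0.2% of probes changed by 1 log2 unit were recovered, 21.8% of those changed by 2, 54.0% by 3 and 75.8% by 4, with 3.1 false calls per run. With the smaller spread of the knockout arrays, the shares were 39.8%, 68.6%, 86.0% and 92.2%, with 8.7 false calls. A list shifted by 1 log2 unit was called by camera in 10 of 10 runs over 12297 genes with either spread. Since the simulated genes were uncorrelated and both groups had equal spread, this does not show how camera behaves on the real lists. There the estimated correlation reached 0.598, in the mitochondrial list.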

Results

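Liver RNA from male mice was measured on 1-colour Agilent mouse expression arrays. Of the 6 arrays, 3 came from wild-type (WT) livers and 3 from livers of mice lacking Gα12, the α subunit of a heterotrimeric G protein that is encoded by Gna12 and acts downstream of cell surface receptors. The labels give an age of 8 weeks, an overnight fast on a chow diet, and a background that is 95% C57BL/6 with 129/Sv as the other strain. The comparison asked which liver transcripts differ when Gα12 is missing. Each array carried 55681 probes, and between 20953 (knockout replicate 2) and 28752 (WT replicate 3) of them were well above background. After the filter on dim probes, 23132 probes remained, and 12297 named genes had at least 1 of them. Levels are log2 signals relative to the 75th percentile of the array, differences are knockout minus WT, and the number of arrays (n = 3 per group) limits their precision.

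Gna12 itself was covered by 1 probe, and only WT replicate 3 had a signal well above background for it. The 3 WT livers had log2 levels of -3.48, -4.55 and -0.89, and the 3 knockout livers had -4.91, -4.62 and -3.47. The group means were -2.97 ± 1.88 (SD, n = 3) in WT and -4.33 ± 0.76 (SD, n = 3) in the knockout. The fitted difference of -1.36 rests mostly on values at background, so it gives no fold, and it did not pass the test in a limma fit over all probes (adjusted p = 0.317). The labels do not say which part of Gna12 was deleted, so the probe is a weak check of the genotype labels, and on WT replicates 1 and 2 it checks nothing.

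The genes that separated the genotypes most clearly were lower in the knockout. Asic5, an acid-sensing ion channel gene that is also called Basic, had a log2 level of 5.36 ± 0.59 (SD, n = 3) in WT and 1.07 ± 0.30 in the knockout, a difference of -4.29 (SE 0.40). Capn3, a calpain protease best known from muscle, was at least 23.8-fold lower in the knockout, where none of the 3 livers had a signal well above background. Ren2, a second renin gene that 129 strains carry and C57BL/6 lacks, differed by -3.17 (SE 0.34), from 0.71 ± 0.31 in WT to -2.46 ± 0.31 in the knockout, whereas the probe for Ren1 differed by -0.02 (SE 0.33). Prelid2 differed by -3.78 (SE 0.37), and the retinol dehydrogenase pseudogene Rdh18-ps was at least 8.64-fold lower. On the other side, the ferritin receptor gene Scara5 was 3.81 (SE 0.59) higher in the knockout, the ganglioside synthase gene B4galnt1 2.73 (SE 0.42), the growth factor gene Bmp7 2.19 (SE 0.37), Ppp1r14a, which encodes an inhibitor of myosin phosphatase, 1.77 (SE 0.32), and the transcription factor gene Creb3l2 2.54 (SE 0.48). For Scara5 and Creb3l2 only 1 of the 3 WT livers had a signal well above background, so the size of these differences is uncertain. The bounds for Capn3 and Rdh18-ps hold for this scaling only, since another scaling gave log2 differences of -2.17 and -1.05.

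In each of these genes every knockout liver lay outside the range of the WT livers, which the rule for naming genes required. None passed the limma test over all probes. The adjusted p was 0.0586 for Asic5, Capn3 and Prelid2, 0.0636 for Rdh18-ps and Ren2, 0.143 for Scara5 and B4galnt1, 0.172 for Bmp7, 0.205 for Ppp1r14a and 0.218 for Creb3l2. Tmc7 and Tox4, which also met the rule for naming genes, had probes that disagreed. For Tmc7, a membrane protein gene, 1 probe was at least 21.1-fold lower in the knockout (limma adjusted p = 0.0586), with a log2 difference of -2.01 under another scaling. The other Tmc7 probe differed by 0.23 (SE 0.41). For Tox4, a DNA-binding protein gene, 1 probe was higher by 4.52 (SE 0.66, limma adjusted p = 0.143) and the other differed by 0.34 (SE 0.41). With the mean over all probes of a gene in place of the brightest, the fit and the adjustment ran over genes, and therefore over fewer tests. Limma then called 7 genes, all lower in the knockout: Asic5, Capn3 and Prelid2 at an adjusted p of 0.0245, Ren2 and Rdh18-ps at 0.0265, and F830016B08Rik and 9930104L06Rik at 0.0293.

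**Figure D1:**
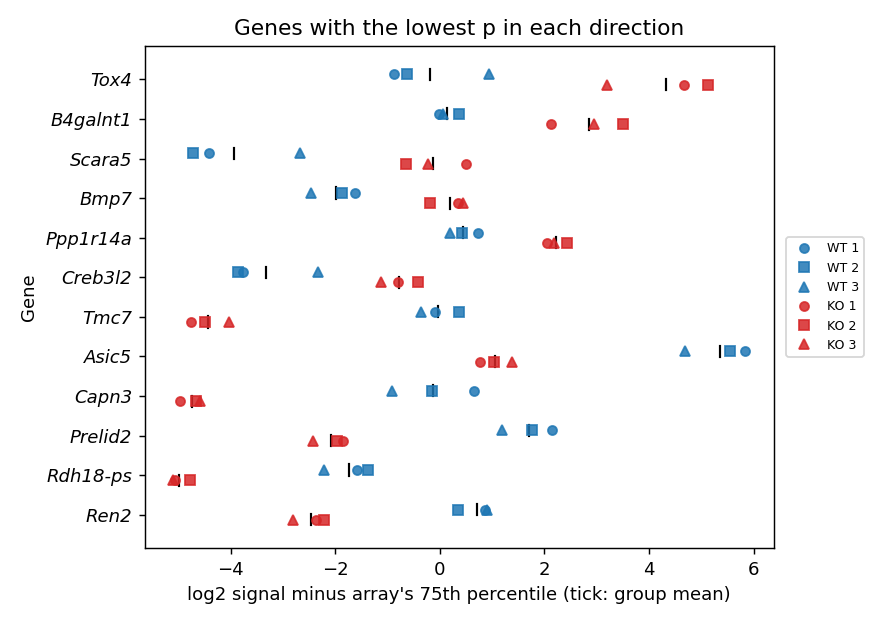
Level of the 12 genes named by rule, 6 in each direction (log2 signal minus the array's 75th percentile, horizontal axis) in each liver, with WT in blue and the knockout in red, a symbol for each replicate and a black tick for each group mean. The rule required that the 3 WT livers and the 3 knockout livers did not overlap. Asic5 lay between 4.70 and 5.84 in WT and between 0.78 and 1.38 in the knockout.

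Over the whole array, limma called 0 of 23132 probes and 0 of 12297 genes at an adjusted p below 0.05, while 4861 probes and 2528 genes had an unadjusted p below 0.05 (1157 probes by chance). Each gene kept the p adjusted over all 23132 probes, by which 8 genes were below 0.1. An adjustment over the 12297 genes alone, which is less strict, was not run for this fit. With trend and robust estimation limma also called 0 probes, with 4916 at an unadjusted p below 0.05. Of the 2528 genes, all of which differed by at least 1.5-fold, 490 were higher and 2038 lower in the knockout, so that 80.6% were lower. With the arrays scaled to the median of the kept probes, 69.5% were lower, and without the filter on dim probes 42.6% of genes and 26.3% of probes. The median difference over all genes was -0.49, and it was -0.36 with that scaling, -0.38 after normexp, -0.21 after quantile normalization and -0.55 in the deposited matrix. The WT and knockout values did not overlap for 3139 genes (25.5%). The 10% expected by chance holds only for arrays that are interchangeable. WT replicates 1 and 2 stood apart from all other arrays, as described next, which can raise this share without an effect of genotype. The share above 10% is therefore not evidence for such an effect.

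The WT livers were not alike. WT replicates 1 and 2 correlated with each other at r = 0.973 across probes, but with the 3 knockout livers only at 0.869 to 0.930, whereas WT replicate 3 correlated with the knockout livers at 0.966 to 0.982. Gapdh, a glycolytic enzyme gene with 7 probes, showed the same division. Its probes spanned 9.58 log2 units on WT replicate 1, 7.79 on WT replicate 2, 4.01 on WT replicate 3 and 4.36 to 4.87 on the knockout arrays. The median SD between livers was 0.65 in WT and 0.19 in the knockout over genes. Without WT replicate 3, limma called 13123 probes, and with any other array left out 0. With WT replicates 1 and 2 left out together, an alternative chosen after seeing the data, it called 0, with 1704 probes at an unadjusted p below 0.05. Correlations within genotypes exceeded those between genotypes by a mean of 0.0299 (exact permutation test, one-sided, p = 0.1, the smallest value 3 against 3 allows).

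**Figure D2:**
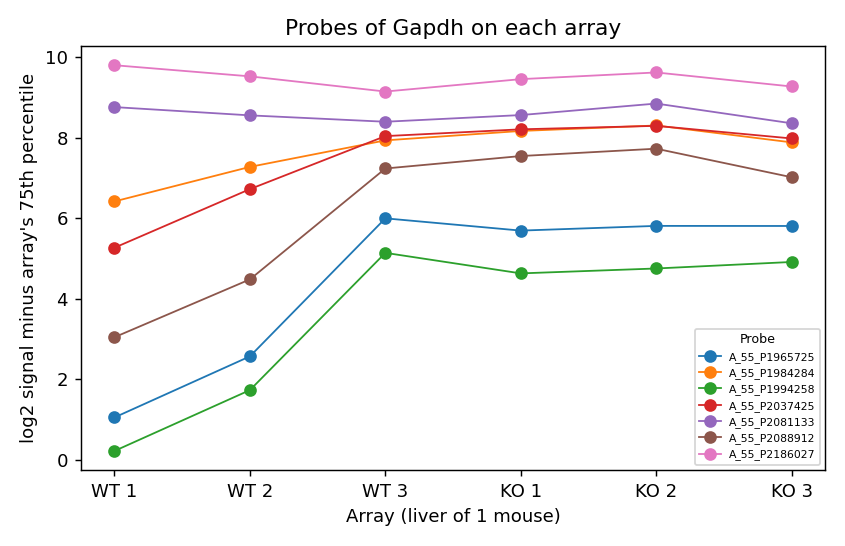
Level of the 7 Gapdh probes (vertical axis, log2 signal minus the array's 75th percentile) on each of the 6 arrays (horizontal axis), with a line for each probe. The lowest probe lay at 0.22 on WT replicate 1 and 1.73 on WT replicate 2, and between 4.63 and 5.14 on the other arrays, while the highest probe lay between 9.14 and 9.80 on all 6.

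At an unadjusted p below 0.05, 2038 of all 12297 genes were lower in the knockout and 490 higher, and the counts of each list below are to be read beside these. Among the gene lists, which were fixed before the data were examined, was a list of heat shock genes and of immediate early genes, which are transcribed within minutes of a stimulus. Nr4a1, an orphan nuclear receptor gene, had a log2 level of 2.88 ± 0.56 (SD, n = 3) in WT and -0.38 ± 0.53 in the knockout, a difference of -3.26 (SE 0.43). Egr1 differed by -3.49 (SE 0.73) and Klf4 by -2.11 (SE 0.52), and Fos was at least 4.65-fold lower in the knockout, where it was not well above background. Under another scaling the log2 difference of Fos was -0.68. WT replicate 3 was above all knockout livers for these 4 genes, with 2.47 for Nr4a1 and 1.72 for Egr1. Of 25 measured members of the heat shock and immediate early list, 0 passed the limma test over all probes, 8 had an unadjusted p below 0.05 (7 lower in the knockout), and these 4 passed when adjusted over the list alone. The list as a whole did not stand apart from other genes in limma's camera test (adjusted p = 0.981), and its median lay -0.01 from that of all genes.

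Acute phase genes differed in opposite directions. Il1b, the gene of the cytokine interleukin-1β, was lower in the knockout by -3.74 (SE 0.72), whereas genes of proteins that the liver secretes in inflammation were higher: Lcn2 (lipocalin 2) by 1.58 (SE 0.34), Saa3 by 1.48 (SE 0.38) and Saa1 (serum amyloid A) by 2.01 (SE 0.57). For Saa1 the levels were 5.69 ± 0.64 (SD, n = 3) in WT and 7.70 ± 0.98 in the knockout, with all 3 WT livers below all 3 knockout livers. Of 36 measured members, 6 were higher and 3 lower at an unadjusted p below 0.05, 0 passed over all probes in limma, and Il1b and Lcn2 passed when adjusted over the list alone. The list's median lay 0.46 above that of all genes, and camera gave an adjusted p of 0.0811 (0.991 with an estimated correlation). The list's median was -0.03, its mean 0.01 and its direction in camera higher, so that their signs differed. With other settings camera's adjusted p ran from 0.000666 with the Gapdh probe spread as a covariate, chosen after seeing the data, to 0.627 without a filter. It was 0.0398 after quantile normalization, 0.0170 in the deposited matrix, 0.0158 with the filter on all 6 arrays, 0.0107 without WT replicate 1 and 0.224 without WT replicate 3, and no list passed with an estimated correlation under any of these settings.

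**Figure D3:**
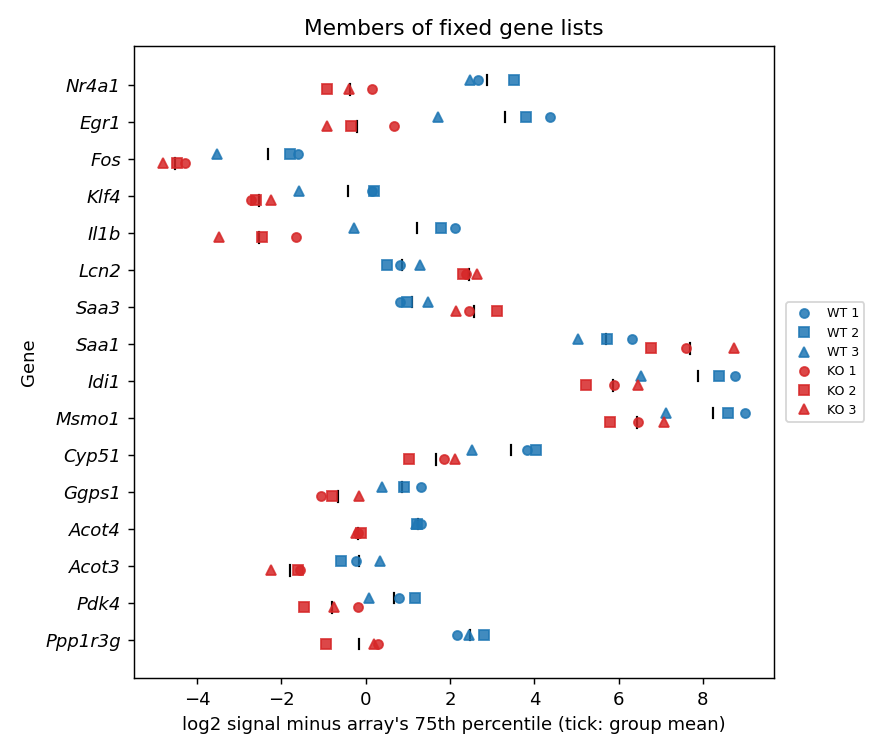
Level of 16 members of the fixed gene lists, picked after their values were seen (log2 signal minus the array's 75th percentile, horizontal axis) in each liver, with WT in blue, the knockout in red, a symbol for each replicate and a black tick for each group mean. Nr4a1, Egr1, Il1b and Acot4 were lower and Lcn2, Saa3 and Saa1 higher in all 3 knockout livers, whereas for Idi1 and Msmo1 WT replicate 3 lay close to the highest knockout liver.

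Genes of lipid use and sterol synthesis had mostly lower values in the knockout. Acot4, a peroxisomal acyl-CoA thioesterase gene and target of the fatty acid receptor PPARα, was at 1.25 ± 0.07 (SD, n = 3) in WT and -0.17 ± 0.05 in the knockout, a difference of -1.42 (SE 0.29), and its relative Acot3 differed by -1.64 (SE 0.38). Pdk4, which spares glucose in fasting, differed by -1.48 (SE 0.46) and the ketone body enzyme gene Bdh1 by -1.46 (SE 0.45). Of 37 measured genes of fatty acid oxidation and ketogenesis, 9 were lower and 0 higher at an unadjusted p below 0.05, and Acot4 passed when adjusted over the list alone. Of 26 genes of sterol synthesis, 13 were lower and 0 higher, among them Idi1 (-2.02, SE 0.63), Cyp51 (-1.79, SE 0.50), Msmo1 (-1.79, SE 0.57) and Ggps1 (-1.53, SE 0.40), and 0 passed over the list alone. The median of the sterol list lay -0.52 from that of all genes and the median of the oxidation list -0.07, so that the latter was close to the difference over the whole array. WT replicates 1, 2 and 3 lay 1.41, 1.40 and 0.47 above the knockout mean in the median of that list, and 0.73, 0.74 and 0.26 in the oxidation list. Neither list passed camera (adjusted p = 0.581 for both), but both were lower in the knockout without WT replicates 1 and 2 (camera adjusted p = 0.0181 for sterol synthesis and 0.0393 for oxidation). That fit has 1 WT liver, and no list passed in it with an estimated correlation (lowest adjusted p = 0.910). Without the filter on dim probes both passed camera as lower (adjusted p = 0.0195 each), again with no list past an estimated correlation (lowest 0.732). That setting compares the lists with many dim probes, whose floor was higher on knockout arrays (-5.14 to -4.82) than on WT arrays (-6.22 to -5.41). The median difference over all genes was then -0.08, so these calls do not show that the lists fell more than other expressed genes.

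Other lipid lists held scattered differences. Vldlr, a lipoprotein receptor gene, differed by -1.88 (SE 0.42) and Angptl8, whose product restrains lipoprotein lipase, by -2.23 (SE 0.60), in a list of 24 genes of which 3 were lower and 1 higher at an unadjusted p below 0.05. Among 27 genes of fatty acid and triglyceride synthesis, 7 were lower, such as Fasn (-1.15, SE 0.39) and Elovl6 (-1.23, SE 0.38), and 2 were higher, Lpin1 (2.76, SE 0.91) and Srebf1 (2.94), which ranged from -3.56 to 0.98 between WT livers. The bile acid list had 5 of 29 members lower, including the ileal-type bile acid transporter gene Slc10a2 (-1.65, SE 0.47), and the lipid droplet list 2 of 18, including Fabp2 (-1.35, SE 0.46). These 4 lists had camera adjusted p-values of 0.618 to 0.775, and 0 of their members passed when adjusted over the list alone.

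In carbohydrate metabolism, Ppp1r3g, a gene for a subunit that directs protein phosphatase 1 to glycogen, was at 2.47 ± 0.31 (SD, n = 3) in WT and -0.15 ± 0.68 in the knockout. The difference of -2.62 (SE 0.42) passed when adjusted over the list alone but not over all probes (limma adjusted p = 0.158). Of 28 measured genes of glucose and glycogen metabolism, 7 were lower and 1 higher at an unadjusted p below 0.05. The list's camera adjusted p was 0.581, and without the filter on dim probes it was 0.0230, lower in the knockout, with no list past an estimated correlation (lowest 0.732). As for the lipid lists, that setting compares with dim probes, whose floor was higher on knockout arrays.

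The list of amino acid and urea metabolism passed camera as higher in the knockout relative to other genes (adjusted p = 0.0172), but not with an estimated correlation (adjusted p = 0.991) nor in fry (adjusted p = 0.630). Its median difference was 0.07, against -0.49 over all genes, and 16 of 30 members were higher. The members with the lowest p were Tat (1.39, SE 0.46), which starts tyrosine breakdown, the ornithine carrier gene Slc25a15 (4.53, SE 1.66), and Arg1 (1.69, SE 0.68), whose enzyme releases urea. For Slc25a15 and Arg1, WT replicate 3, at 1.24 and 7.84, lay among the knockout livers, and WT replicates 1 and 2 lay below them, for Slc25a15 at background. The call was lost without WT replicate 1 (adjusted p = 0.0544) and without WT replicates 1 and 2 (adjusted p = 0.726).

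Genes expressed at different levels in male and female mouse livers formed a pair of lists, which were not compared with each other. The male-biased list passed camera as higher in the knockout relative to other genes (adjusted p = 0.0172), but not with an estimated correlation (adjusted p = 0.991) nor in fry (adjusted p = 0.486), and without WT replicate 3 its adjusted p was 0.224. Scara5, described above, and Moxd1, a monooxygenase-like gene (5.19, SE 1.15, above background in 1 WT liver), passed when adjusted over the list alone, and the complement gene C6 was higher by 1.60 (SE 0.46). The list's median of -0.15 and its mean of 0.48 differed in sign, and 4 of 21 members were higher and 0 lower at an unadjusted p below 0.05. Among 14 measured female-biased genes, Atp6v0d2 (-1.97, SE 0.36), Acot3 and Abcd2 were lower and Cyp17a1, a steroid hydroxylase gene, was higher (2.86, SE 0.86), and these 4 passed when adjusted over the list alone. Abcd2, a peroxisomal fatty acid transporter gene, was at least 4.86-fold lower in the knockout, with a log2 difference of -0.70 under another scaling. That list's camera adjusted p was 0.967.

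Drug-metabolising genes had differences in either direction, as did genes over the whole array (2038 of 12297 lower and 490 higher at an unadjusted p below 0.05). Of 42 measured cytochrome P450 and phase I genes, 7 were lower and 2 higher at an unadjusted p below 0.05, including Cyp2g1 (-1.43, SE 0.33) and the nuclear receptor gene Nr1i3 (-0.95, SE 0.32), which encodes CAR. Of 38 NRF2 targets and conjugating enzymes, 9 were lower and 2 higher, including the glutathione synthesis gene Gclc (-1.41, SE 0.38). Ugt1a6a was at least 2.93-fold lower, with a log2 difference of -0.39 under another scaling. In the growth hormone and insulin list, Klb, the FGF21 co-receptor gene, differed by -1.28 (SE 0.33) and Irs2 by -1.01 (SE 0.36), with 4 of 23 members lower and 1 higher. These 3 lists had camera adjusted p-values of 0.929 to 0.981. In WT replicate 1 the medians of the P450, NRF2 and growth hormone lists lay 0.54, 0.91 and 0.81 above the knockout mean. They lay 0.69, 0.67 and 1.05 above it in WT replicate 2, and 0.19, 0.11 and -0.02 from it in WT replicate 3.

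Of 19 SRF and YAP target genes, which follow actin dynamics and cell tension, 1 was lower at an unadjusted p below 0.05, the smooth muscle gene Cnn1 (-1.20, SE 0.38). Camera gave that list an adjusted p of 0.981.

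Among stress, clock and organelle genes, the list medians lay closer to the knockout mean in WT replicate 3 than in WT replicates 1 and 2. For p53 targets the median in WT replicate 3 still lay 0.30 above that mean, against 0.89 and 0.91 in WT replicates 1 and 2. The chaperone genes Pdia4 (4.19, SE 1.43) and Sdf2l1 (3.83, SE 1.37) were high in the knockout and in WT replicate 3, at 3.19 and 3.32, and low in the other WT livers, whereas Dnajb9 was higher in all 3 knockout livers than in all 3 WT livers, by 0.88 (SE 0.31). Of 28 genes of the unfolded protein response, 4 were higher and 1 lower at an unadjusted p below 0.05. Of 54 measured mitochondrial genes, 6 were lower, among them Sirt1 (-1.60, SE 0.54) and Tfam (-1.17, SE 0.41), and 2 higher. The medians of that list lay 1.29 and 0.96 above the knockout mean in WT replicates 1 and 2, and -0.15 from it in WT replicate 3. The death receptor gene Fas differed by -1.82 (SE 0.51), among 17 p53 targets with 5 lower, and the lysosomal gene Lamp2 by -1.34 (SE 0.45), among 28 autophagy genes with 4 lower. Of 20 clock genes, 2 were lower and 2 higher. The unfolded protein, mitochondrial, p53, autophagy and clock lists had camera adjusted p-values of 0.581 to 0.775.

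**Figure D4:**
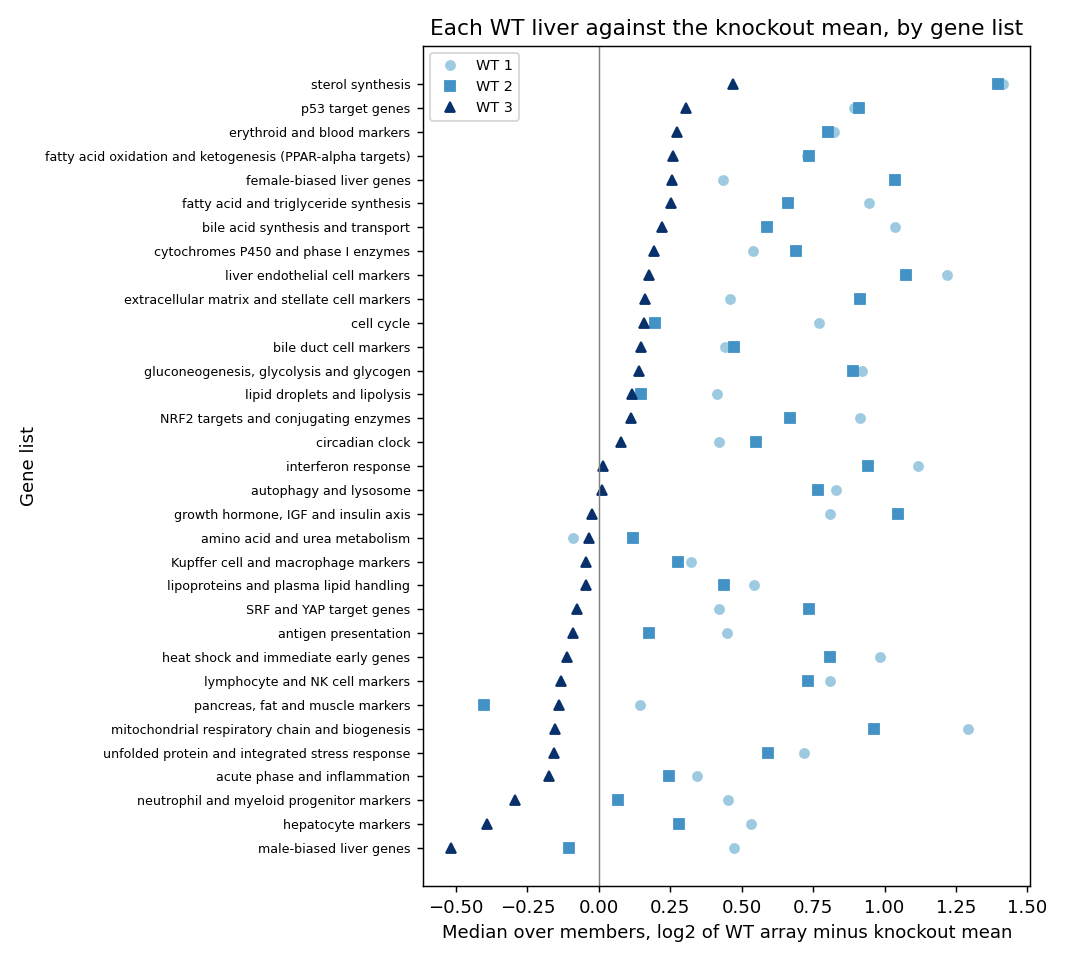
Median over the measured members of each gene list shown (vertical axis) of the level in 1 WT liver minus the mean of the 3 knockout livers (horizontal axis, log2), with a symbol for each WT liver. WT replicate 3 lay between -0.52 (male-biased genes) and 0.47 (sterol synthesis), while WT replicate 1 reached 1.41.

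Markers of liver cell types differed in either direction, as did genes over the whole array (2038 of 12297 lower and 490 higher at an unadjusted p below 0.05). In the endothelial list, Wnt2, which zonal endothelium makes, was at least 2.72-fold lower in the knockout and passed when adjusted over the list alone. Under another scaling the log2 difference of Wnt2 was -0.49. Fcgr2b was lower by -1.23 (SE 0.43), but Cdh5 was higher by 2.40 (SE 0.81) and Kdr by 2.28 (SE 0.67). Of the 23 members, 8 were lower and 2 higher at an unadjusted p below 0.05. For Kdr and Cdh5 the difference was 0.81 and 0.47 without WT replicates 1 and 2, which carry most of it, and Kdr in WT replicate 3 (4.23) lay within the range of the knockout livers. Stellate cell and matrix genes had 4 of 25 lower, including Lrat (-1.42, SE 0.43) and Hgf (-1.18, SE 0.37), and 2 higher, including Col4a2 (1.60, SE 0.55). Kupffer cell markers had 1 of 20 lower, Msr1 (-0.93, SE 0.37), and 1 higher, C1qa (1.42, SE 0.58). Lymphocyte markers had 2 of 17 lower, bile duct markers 2 of 12, including Krt23 (-1.17, SE 0.40), and erythroid markers 2 of 10, including Hbb-b2 (-1.16, SE 0.45). Neutrophil markers had 0 of 7 members at an unadjusted p below 0.05 in limma. Of 14 pancreas, fat and muscle markers, 1 was higher, the muscle actin gene Acta1 (2.58, SE 0.76), which varied between knockout livers from -2.45 to 0.53. Without knockout replicate 1 that list passed camera as higher in the knockout (adjusted p = 0.0122), with no list past an estimated correlation (lowest 0.998). The muscle genes Mb and Tnnt3 were likewise higher in knockout replicates 2 (-1.97 and -2.07) and 3 (0.07 and -0.01) than in replicate 1 (-5.07 and -3.47). Hepatocyte markers had 2 of 31 higher, Tat and Cebpa (2.28, SE 0.92), and 1 lower, and for Cebpa the difference was -0.07 without WT replicates 1 and 2. Interferon genes had 6 of 34 lower, such as Stat2 (-1.56, SE 0.53), and 2 higher, antigen presentation genes 1 of 15 lower, H2-Q4 (-1.72, SE 0.61), and cell cycle genes 2 of 25 lower, including Rrm1 (-0.95, SE 0.38). Camera gave adjusted p-values of 0.135 to 0.950 for these 12 lists. Without WT replicates 1 and 2 the difference was -0.33 for Stat2, -0.46 for Fcgr2b, -0.27 for Hbb-b2, -0.54 for Krt23 and 0.44 for Col4a2. It was 0.32 for C1qa, -0.46 for Msr1, -0.30 for Rrm1 and -0.80 for Lrat. For H2-Q4 (-1.25), Wnt2 (-1.24) and Acta1 (1.98) it stayed above 1 log2 unit in size, although smaller for H2-Q4 and Acta1 than with all arrays. Only for Hgf (-1.58) did these values show a larger difference than with all arrays. The median of the interferon list lay 1.12, 0.94 and 0.01 above the knockout mean in WT replicates 1, 2 and 3.

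Genes beside Gna12 on chromosome 5 were looked at as a set, since a targeted allele can carry neighbouring sequence of the strain it was made in. Of the 100 measured genes nearest to it, 13 had an unadjusted p below 0.05, against 20.6% of the other genes (Fisher's exact test, two-sided, p = 0.0624). The neighbours with the lowest p were Prkar1b, at least 3.29-fold lower in the knockout, where it was not above background, and the zinc finger gene Zfp113 (-1.05, SE 0.29), both lower in all 3 knockout livers. With 20 genes as the limit the share was 15.0% (Fisher's exact test, p = 0.782), and with 200 it was 11.3% of 177 genes (Fisher's exact test, p = 0.00139). With any array left out the p for the 100 nearest genes was 0.581 to 0.914 (Fisher's exact test), and camera gave the 100 genes a p of 0.497.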

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

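The alternatives that leave out WT replicates 1 and 2 together or add the Gapdh probe spread as a covariate were chosen after seeing the data. Counts of 0 probes and 0 genes past limma's threshold, with genes by the p adjusted over all probes, were also found after quantile normalization, median scaling, the series matrix, no filter, trend and robust estimation, the replicate block, both added alternatives and 5 of 6 arrays left out in turn, with 1540 to 16654 probes at an unadjusted p below 0.05. Probes called were 1 with normexp (Asic5) and 2 with the filter on all 6 arrays (Asic5 and Prelid2), and the gene counts were the same. The mean over probes called 7 genes. Array weights called 18135 probes and 10012 genes, but their estimation did not converge and gave WT replicate 2 a weight of 42.9 and WT replicate 3 a weight of 0.0664. Leaving out 1 array gave 0 to 13123 probes and 0 to 7645 genes, the highest without WT replicate 3. Genes past an unadjusted p of 0.05 and 1.5-fold numbered 5492 without a filter, 8516 with array weights, 773 without WT replicates 1 and 2, 947 with the Gapdh covariate and 706 to 8194 with 1 array left out. Gene lists past camera numbered 1 with normexp, 3 after quantile normalization and in the series matrix (with acute phase genes as the third), 4 without a filter (all lower in the knockout: mitochondrial, oxidation, sterol synthesis and glucose metabolism), 0 with array weights, 6 without WT replicates 1 and 2, 5 with the covariate, 0 with an estimated correlation, 0 in fry and 1 to 3 with 1 array left out. The estimated correlation called 0 lists under every setting where it was run. The 4 lists called without a filter were compared with many dim probes, whose floor was higher on knockout arrays. The adjusted p of the amino acid list was 0.0614 with normexp, 0.561 without a filter, 0.0762 with array weights, 0.726 without WT replicates 1 and 2, 0.253 with the covariate, 0.991 with an estimated correlation, 0.630 in fry and 0.0105 to 0.0544 with 1 array left out. That of the male-biased list was 0.355 without a filter, 0.0625 with the filter on all 6 arrays, 0.0762 with array weights, 0.991 with an estimated correlation, 0.486 in fry and 7.24e-06 to 0.224 with 1 array left out, and with WT replicates 1 and 2 left out it was 2.62e-06. The mitochondrial list was higher in the knockout without WT replicates 1 and 2 (adjusted p = 0.00846) and with the covariate (0.412), and lower in all other fits, past the threshold without a filter (0.00490). Gna12 differed by 0.10 with array weights, by -2.15 to -0.32 with 1 array left out, and was lower in the knockout in the other fits. The share beside Gna12 had a p of 0.0275 after quantile normalization, 0.00139 with 200 genes and 0.581 to 0.914 with 1 array left out. The excess of correlation within genotypes was 0.0149 to 0.0737 with 1 array left out. Same-numbered arrays did not deviate together (correlations of -0.13, 0.01 and -0.04), and with the replicate block limma called 0 probes and 0 genes and camera 2 lists. The slide block was not run. The causes were not tested. The mean over probes changed the fit as well as the number of tests, with an SE for Asic5 of 0.38 against 0.40. Signal over background limits Gna12, the genes given as lower bounds, and genes above background on 1 WT array (Scara5, Creb3l2, Moxd1, Slc25a15, Acta1, Mb and Tnnt3).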

Other observations

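The tests of patterns below, except the counts of genes, probes and lists over other splits, were chosen after the results they measure had been seen, wholly or in part. In WT replicate 3, the liver closest to the knockout livers, 10 genes were over 8-fold higher and 9 over 8-fold lower than the knockout mean. Besides the genes already named, the higher ones included Lrtm1 (2.69 in WT replicate 3, and 0.78, -1.55 and -0.76 in the knockout) and the class I histocompatibility-like gene Gm8909 (3.34, against -1.51, 1.98 and -1.46). The lower ones included Syt10, a synaptotagmin gene (1.63 in WT replicate 3, and 5.53, 6.56 and 3.35 in the knockout), the dynamin gene Dnm1 (1.21, against 4.61, 5.56 and 2.65), the muscle troponin gene Tnnc2 (-3.28, against -2.13, 0.42 and 1.72) and Saa2, an acute phase gene (3.93, against 7.24, 6.40 and 8.46). Of the 10 higher genes, 10 were also higher by over 1 log2 unit in both WT replicates 1 and 2 (30.6% of all genes were), and of the 9 lower genes, 8 were also lower (8.25% of all genes), but these genes were picked against the same knockout mean. All of these genes were chosen after their values were seen. Set against the mean of the other knockout livers, knockout replicates 1, 2 and 3 differed over 8-fold in 41, 37 and 30 genes. That mean covers fewer livers, but the counts for WT replicate 3 did not exceed those between single knockout livers.

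Under the alternatives that limit the weight of WT replicates 1 and 2, which both rest largely on WT replicate 3 against the same knockout livers, camera placed 5 lists beyond its threshold, and without these arrays also the mitochondrial list (higher in the knockout, adjusted p = 0.00846, and 0.412 with the covariate). Leaving out both arrays, hepatocyte markers (adjusted p = 0.000472), male-biased genes (2.62e-06) and acute phase genes (0.0204) were higher in the knockout, and sterol synthesis (0.0181) and fatty acid oxidation (0.0393) lower. With the Gapdh probe spread as a covariate, the same 5 lists had adjusted p-values of 5.10e-05, 9.36e-08, 0.000666, 0.00316 and 0.0494 in the same directions. None passed with an estimated correlation under either alternative, where the lowest adjusted p was 0.910 and 0.250, and the first alternative rests on 1 WT liver that is assumed to vary like the knockout livers.

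WT replicates 1 and 2 stood apart from the other 4 arrays, 3 technical explanations were tested, and a biological difference between the WT mice was not tested and remains open. Over 392 genes with at least 3 kept probes, the median range between a gene's probes of the deviation from the knockout mean was 2.18 on WT replicate 1 and 1.66 on WT replicate 2 against 0.46 on WT replicate 3, a ratio of at least 3.57, where the SD of all deviations was 2.67 and 2.09 times that of WT replicate 3. Relative to ranges with gene names shuffled among the same probes it was 0.863 and 0.929, against 0.678 to 0.708 on the other arrays, so that probes of a gene deviated less together, whereas the correlation between a gene's brightest probes (0.308 and 0.293) was below that of WT replicate 3 (0.404) but no lower than the lowest knockout array (0.209 to 0.294), and RNA of lower integrity may account for the pattern, as may other causes of disagreement between probes. For labelling, hybridisation or scanning, spike-in transcripts deviated with SDs of 0.209 and 0.188 on WT replicates 1 and 2, against 1.59 and 1.25 for liver probes of the same brightness. The spike-in SD was 0.0953 on WT replicate 3, and 0.0447 to 0.0667 on the knockout arrays, which enter the mean used. The ratios to liver probes (0.132 and 0.150) lay within those of the other arrays (0.0849 to 0.183), and each spike-in value is a median over its spots. The ratio therefore cannot decide, and a technical share stays open. A wrong label on WT replicate 3 stays open: its Gna12 signal lay at least 2.58 log2 units above the highest knockout liver, but this is 1 probe, at background in all knockout livers and in WT replicates 1 and 2, and Asic5, at 4.70 in WT replicate 3, 5.55 and 5.84 in the other WT livers and 0.78 to 1.38 in the knockout, goes against it but was picked for that difference.

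The genes that differed between WT replicate 3 and all knockout livers may reflect genotype, strain, slide row or single animals. When genes over 8-fold lower than in WT replicate 3 were chosen in each knockout liver in turn, 70.2% of the choices were also lower by over 1 log2 unit in the mean of the other knockout livers than in both WT replicates 1 and 2, against 30.2% of choices between knockout livers and 29.8% to 31.1% of all genes, but short of the 75% asked for, which leaves single animals open. With each gene counted once and each remaining knockout liver taken alone, 15 of 32 genes (46.9%) were so in every choice, against 15.2% to 26.4% of genes chosen between knockout livers, which faced fewer choices. Because Ren2 is present in 129 strains and absent from C57BL/6, chromosome segments of another strain are a candidate explanation. The Ren2 signal was the higher one in WT (0.86, 0.36 and 0.91, against -2.37, -2.21 and -2.81 in the knockout). Under this explanation, genes past an unadjusted p of 0.01 would crowd on some chromosomes. The permutation p for an uneven spread was 0.0704 for 351 of 12293 named genes and 0.297 for 212 of 3309 noncoding probes named by coordinates. Chromosome X was highest in both (4.62% and 11.8%, against 2.86% and 6.41% over all chromosomes). What would count against segments was revised more than once after these values were known. Since an uneven spread was neither shown nor excluded, strain, slide row, the loss of Gα12 and single animals cannot be told apart here.

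The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. Limma called 0 genes and 0 probes in the real split and at most 0 in the others. That 10 of 10 splits gave as many of each was fixed in advance by the real count of 0 and tells nothing. An unadjusted p below 0.05 was reached by 4861 probes in the real split and by 53 to 4030 in the others. At that p and 1.5-fold, the real split gave 2528 genes and the highest other 2115, from WT replicates 1 and 2 with knockout replicate 3, and 1 of the 10 splits gave as many as the real one. Camera called 2 lists in the real split and 10 in the highest other, which set WT replicate 1 with knockout replicates 2 and 3, and 8 of the 10 splits gave as many. The 3 splits that set WT replicate 1 with 2 knockout livers gave 7 to 10 lists with only 53 to 129 probes at an unadjusted p below 0.05, which may come from a structure of the arrays other than genotype or from a preset correlation too small for these lists, and no test separated these.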
